A study of Oryza sativa Japonica Group with 8 samples.

How the data were processed

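The material was rice (Oryza sativa cv. Nipponbare) roots. Per the labels' protocols, plants were 12 days old when each received 250 juveniles (stage 2) of the nematode Meloidogyne graminicola, or a mock inoculation, and tissue was taken 7 and 14 dai, fixed, and cut on a cryostat. Giant cells and vascular cells were isolated by laser microdissection. RNA was extracted with a kit for small samples and amplified as cDNA with the Ovation RNA-Seq System, and fragments of about 300 bp (within 50 bp) were sequenced on a paired-end flow cell, each sample in 2 of 4 lanes. Amplification copies molecules, and no molecular identifiers are named, so counting intervals and floors cover counting error only.

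The deposited table holds whole-number read counts per feature, which the authors did not normalise as far as the values show. It has 74189 features: 55986 gene models and 18203 unannotated regions. The submitters' processing notes name TopHat 1.3.1 and Cufflinks 1.0.3. The genome build, the annotation, the counting tool and its use of strand are not given in the sources used here, so coordinates are those of the table, antisense or overlapping genes may share reads, and gene names are the table's own descriptions. The table's identifiers had no match in the reference gene list. Columns are numbered 1 and 4 where the sample titles are numbered 1 and 2, so a column gives the group and not the title's replicate; 0 columns were left unmapped. The labels' time points 1 and 2 were taken as 7 and 14 dai from the order of the design text. Of 30624 features with at least 50 counts in all, 303 share identical counts with another feature and cannot be told from their copy.

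The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. edgeR 4.0.16 (quasi-likelihood F test, TMM factors, robust) in R 4.3.3 was fitted to the counts of gene models with CPM of at least 1 in at least 2 libraries. All 8 libraries entered, with a coefficient per group and no block. P-values were adjusted by Benjamini-Hochberg, with calls at an adjusted p under 0.05, two-sided. Contrasts were giant against vascular cells at 7 dai, at 14 dai and averaged over both, the difference of the contrasts of both days, and 14 against 7 dai within each cell type. Adjusted p-values of genes are edgeR's and those of lists are from camera in limma 3.58.1 (voom weights, preset correlation 0.01, Benjamini-Hochberg over 33 lists). Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. None of the list calls of camera held with an estimated correlation. Fry's reference is no change and not the other genes. In the mean of both days it passed aquaporins downward (adjusted p = 0.00983), and DNA replication (0.00118) and photosynthesis (0.00983) upward. Of camera's lower lists it did not pass peroxidases (0.146), pathogenesis-related (0.687), phenylpropanoid (0.253) or jasmonate genes (0.443). Nor did it pass trehalose synthesis (0.469), xylem markers (0.0774) or WRKY factors (0.329), and it put transposon models higher (0.0097). Normalised CPM use TMM factors, which ran from 0.622 to 1.588; group values are means with SD.

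Of 35 lists defined by words in the gene descriptions, organelle-encoded proteins had no member and root hair and epidermis fewer than 5 tested members. The named-gene rule took up to 8 genes per direction by fold change with a group mean of at least 10 CPM, a described function and full separation of the libraries (4 by smallest p if none passed), and the 2 members of smallest p from each list. For 14 against 7 dai and the day difference it took 3 per direction. Lists and rule were planned for the 7 dai, 14 dai and day-difference contrasts and extended to the mean of both days and to 14 against 7 dai. A fold against a group at 0 in all libraries was set against a floor of 3 counts per library, and no fold is given where the highest library of a group had 1 to 3 counts. In the mean of both days no fold is given for a gene at 0 in both libraries of a day, although list medians use its fitted value. Chosen after seeing the data, list medians of that contrast were set against 10000 random lists drawn from the same 20 bins of mean log2 CPM. Random members were drawn independently, so the percentiles take no account of correlation between members of a list. Library measures were compared by two-sided exact permutation tests.

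The replicate numbers gave no sign of pairing: deviations of same-numbered libraries from their group means correlated at -0.038 to 0.056. Vascular replicates correlated at only 0.547 and 0.51, so noise between libraries could hide a shared effect, and pairing remains unknown. Alternatives were the replicate number as a block, no filter on low counts, a filter at 5 CPM, DESeq2 size factors, upper-quartile factors, DESeq2 1.42.0 as the test, the 4 libraries of a day alone, and each library left out in turn. Chosen after seeing the data were limma with a spread per cell type, fits with unannotated regions or without the 2 highest gene models, libraries rescaled so that the all-gene median of the mean contrast was 0, and fits to 1 cell type.

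The procedure was tested on simulated counts for the real genes with 200 changed. The changed genes were drawn from those averaging at least 10 CPM, with as many raised as lowered. Changes in weakly expressed genes, and calls mostly in 1 direction as in the real data, were not simulated. For the mean of both days, with a spread per gene (15707 genes tested), edgeR made 82 calls of which 8 were false, and recovered 0% of 4-fold, 38.8% of 16-fold and 72.7% of 64-fold changes. With a spread per gene and cell type (15754 genes) it made 53 calls, 2 false, and recovered 0%, 16.4% and 60.6%. DESeq2 made 343 calls in the former, 225 of them false, and 699 in the latter, 575 false. For the 7 dai contrast edgeR made 24 calls (1 false) and 0 calls, and DESeq2 302 (225 false) and 509 (440 false). A list with changed genes was called in all 4 simulated settings (2 contrasts in each of 2 simulations), and 0 of 10 random lists in each. Genes were simulated independently of each other, so this does not test list calls where members correlate. In the mean of both days the estimated correlation was 0.494 for xylem markers, 0.211 for photosynthesis and 0.136 for pathogenesis-related genes, and -0.004 for aquaporins. Summaries and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.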

Results

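Giant cells are the enlarged, multinucleate feeding cells that root-knot nematodes induce inside the vascular tissue of a host root. RNA from giant cells induced by Meloidogyne graminicola in roots of the rice cultivar Nipponbare, and from vascular cells of mock-inoculated roots, was sequenced after laser capture on day 7 or day 14 of infection (dai, days after inoculation). Each combination of cell type and day had 2 libraries, 8 in all, named here by cell type, day and the number in their column (1 or 4). Gene models received 17677454 to 20130796 counts per library. The labels call the libraries of a group biological replicates but do not tie captured regions to plants, so some captures may share a plant, and the p-values below measure the spread between these libraries only.

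Counts were recorded on 25480 ± 1780 gene models per giant cell library (SD, n = 4) and on 16210 ± 2150 per vascular library (SD, n = 4). The ranges did not overlap, with a two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow, and an adjusted p = 0.05 over 7 library measures. A pair of neighbouring models described only as expressed proteins, LOC_Os09g00999 (chromosome 9, 2874 to 5458) and LOC_Os09g01000 (chromosome 9, 6384 to 9310), took 53.7% to 71.6% of gene-model counts in vascular libraries and 44.65% to 58.84% in giant cell libraries. Across genes, log2 values of the replicates correlated with r = 0.891 in giant cells at 7 dai and 0.804 at 14 dai, and with 0.547 and 0.51 in vascular cells; genes are not independent replicates. Of the models averaging at least 10 CPM (counts scaled to library size) in a group, 13.34% at 7 dai and 15.2% at 14 dai had 3 or fewer counts in 1 of the 2 vascular libraries. The matching share in giant cells was 0 of 7190 at 7 dai and 0.06% at 14 dai. The biological coefficient of variation was 0.567 within giant cells and 1.62 within vascular cells. Vascular 14 dai replicate 1 stood apart, with the fewest detected models (13727), the largest share in the 2 highest models (71.6%) and the lowest TMM factor (0.622). On principal component 2 of log2 CPM (19.34% of the variance) it lay at -282.3, and the other vascular libraries at 108.2 to 133.6.

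**Figure D1:**
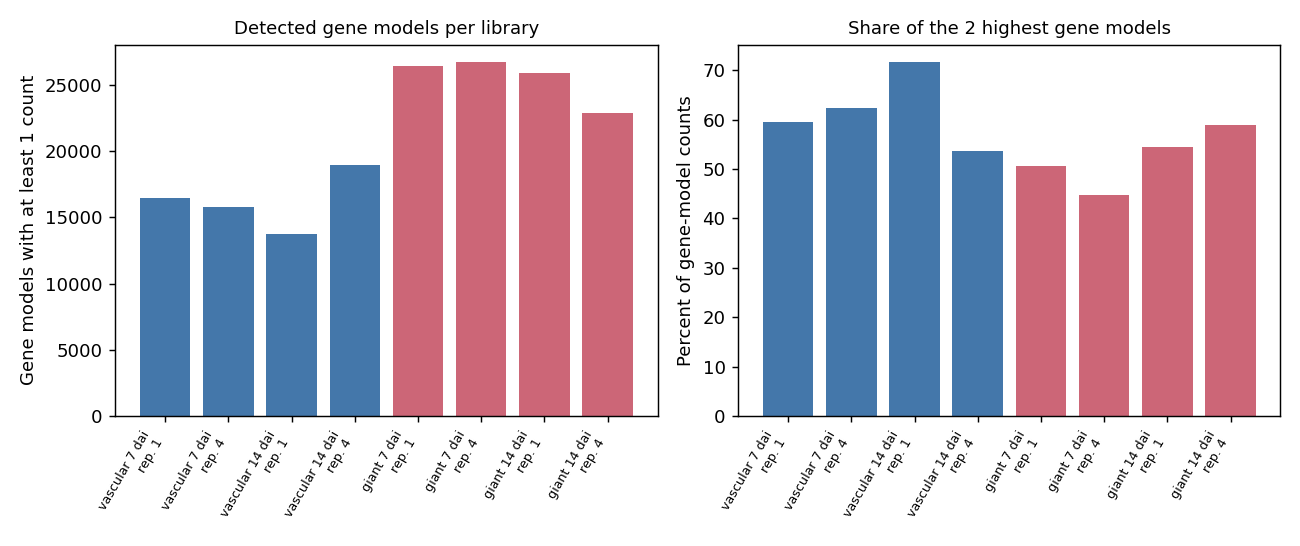
Left, number of gene models with at least 1 count in each of the 8 libraries; right, percent of gene-model counts in the 2 highest models, with vascular libraries in blue and giant cell libraries in red. Giant cell libraries detected 22861 to 26706 models and vascular libraries 13727 to 18929.

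Genes that separate giant cells from vascular cells at both days were sought in the mean of the 7 and 14 dai contrasts. All giant cells came from inoculated roots and all vascular cells from mock-inoculated roots. In every giant to vascular contrast, an effect of cell type therefore cannot be told apart from an effect of infection on the root. The secreted class III peroxidase LOC_Os10g02070 (chromosome 10, 677086 to 678882) averaged 1.48 ± 1.06 CPM in giant cells and 316 ± 39.7 in vascular cells (SD, n = 4 each), a log2 fold change of -7.77 (SE 0.82, edgeR adjusted p = 0.00427). The aquaporin LOC_Os02g57720, of a family of water channels (chromosome 2, 35349673 to 35351454), averaged 0.316 ± 0.267 against 159 ± 194 CPM (log2 -8.69, SE 0.99, adjusted p = 0.00501). An amino acid transporter, LOC_Os02g54730 (chromosome 2, 33511971 to 33517881), went the other way, with 55.0 ± 27.6 CPM in giant cells and 0.0565 ± 0.0653 in vascular cells, where no library held more than 2 counts (adjusted p = 0.018). In each of these 3 genes all 4 giant cell libraries lay on the same side of all 4 vascular libraries. Of 17373 gene models tested, 2839 were higher and 716 lower in giant cells, 3555 in all. Fold changes are the average of the log2 folds of both days, and so can differ from the log2 ratio of the means over 4 libraries.

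That count depended on single giant cell libraries: without giant 7 dai replicate 1 it was 37 (11 higher, 26 lower), without giant 7 dai replicate 4 it was 62 (19 higher, 43 lower), without giant 14 dai replicate 1 it was 1235 (1117 and 118), and without giant 14 dai replicate 4 it was 1306 (1158 and 148). The fit shares 1 spread per gene over both cell types, so leaving out a giant cell library also changes that spread. The all-gene median stayed at 0.93 without giant 7 dai replicate 1 and 0.9 without giant 7 dai replicate 4. The biological coefficient of variation was 1.14 over all 8 libraries and 1.62 within vascular cells. The p-values thus rest on a smaller spread than that of the vascular libraries. Models with at least 5 CPM gave 1538 calls, 68.1% of them higher against 79.9% with the filter at 1 CPM. DESeq2 called 6184 (4685 higher, 1499 lower) and limma with a spread per cell type 369 (25 higher, 344 lower). With libraries rescaled so that the all-gene median was 0, chosen after seeing the data, 1971 were higher and 1303 lower (60.2% higher). Genes named from this contrast that kept their call without either of the 7 dai giant cell libraries were LOC_Os10g02070, LOC_Os02g57720, LOC_Os02g54730, LOC_Os03g16960, LOC_Os07g35560, the ycf3 copies LOC_Os01g57966 and LOC_Os10g21254, and the transposon models LOC_Os07g23640 and LOC_Os06g41740. The median log2 fold change over all tested models was 0.98 (0.98 with genes at 0 in either cell type set to their bound), and 1.19 with upper-quartile scaling. It was 1.65 without vascular 7 dai replicate 1, 1.70 without vascular 7 dai replicate 4, 2.42 without vascular 14 dai replicate 4, 1.89 with limma and 0.41 for models with at least 5 CPM. In each of these the median lay above 0 and list tests compare a list with all other genes.

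The cysteine-rich repeat secretory protein 55 LOC_Os03g16960 averaged 0.166 ± 0.139 CPM in giant cells and 260 ± 372 in vascular cells (log2 -10.32, SE 1.60, adjusted p = 0.0201; SD, n = 4). A serpin, LOC_Os03g41438, averaged 0.103 ± 0.136 against 44 ± 54.4 CPM, and a receptor-like kinase of the SHR5 type, LOC_Os05g16920, 0.127 ± 0.196 against 48.4 ± 60.7 (both adjusted p = 0.0269). The chitinase CHIT7, LOC_Os06g51050, reached at most 2 counts in any giant cell library and averaged 56.9 ± 59.0 CPM in vascular cells. Nicotianamine synthase LOC_Os03g19427, which makes a metal chelator, was at 0 in all giant cell libraries and averaged 37.0 ± 55.7 CPM in vascular cells, at least 287-fold lower against a floor of 3 counts per library (adjusted p = 0.0269).

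Other genes named by the rule were detected in giant cells and at or near 0 counts in vascular libraries. Pyruvate kinase LOC_Os01g47080, a glycolytic enzyme, averaged 11 ± 3.83 CPM in giant cells and 0 in vascular cells, at least 53.1-fold higher against the same floor. The glycolytic phosphoglycerate kinase LOC_Os06g45710 averaged 27.0 ± 3.36 against 0.0804 ± 0.11 CPM. The large subunit of glucose-1-phosphate adenylyltransferase, which makes the precursor of starch, LOC_Os05g50380, averaged 29.6 ± 25.7 against 0.0874 ± 0.175. The latter 2 genes were at 0 in both vascular libraries at 7 dai, so no fold averaged over the days is given. A DEAD-box RNA helicase, LOC_Os05g05810, was at least 51.4-fold higher, a WD-repeat protein, LOC_Os03g58570, at least 61.6-fold, and CPuORF26, LOC_Os05g47540, at least 74.7-fold. All 6 genes had an edgeR adjusted p = 0.0269. Each of these 6 calls was lost without giant 7 dai replicate 1, and 9 of the 63 called genes named by rule kept theirs (10 without giant 7 dai replicate 4, 35 without giant 14 dai replicate 1 and 32 without giant 14 dai replicate 4), all 63 in the same direction. Leaving out vascular libraries kept 54 of 62 to 59 of 61 of them. Their folds moved by over 1.5 times in 10 (without vascular 7 dai replicate 1), 15 (vascular 7 dai replicate 4), 11 (vascular 14 dai replicate 1) and 18 (vascular 14 dai replicate 4), and in 4 to 9 without a giant cell library. Separation of the libraries was part of the rule that named most of these genes; WRKY28, CESA9 and the gibberellin oxidase LOC_Os01g55240, named below from fixed lists, did not separate the 4 giant cell from the 4 vascular libraries.

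Water channels and wall peroxidases had more members lower than higher, and both lists kept camera's call with each library left out. Fry passed aquaporins (adjusted p = 0.00983) but not peroxidases (adjusted p = 0.146). Of 20 aquaporins tested, 7 were lower and 3 higher in giant cells (10 and 3 adjusted over the list alone), with a median log2 fold change of -3.32 (camera adjusted p = 1.31e-05, and adjusted p = 0.172 with an estimated correlation). LOC_Os02g13870 held at most 3 counts in a giant cell library and averaged 29.1 ± 23.6 CPM in vascular cells (SD, n = 4). The 3 aquaporins called higher were LOC_Os08g05600, LOC_Os10g36924 and LOC_Os03g20410, chosen after their values were seen, at means of 1.58, 5.28 and 1.55 CPM in giant cells. Of 37 class III peroxidases, 8 were lower and 4 higher (13 and 6 adjusted over the list alone; median -2.12, adjusted p = 5.49e-05, and adjusted p = 0.374 with an estimated correlation). The peroxidase LOC_Os08g02110 averaged 0.623 ± 0.355 against 90.5 ± 81.7 CPM (log2 -6.91, SE 1.04, adjusted p = 0.018). Markers of xylem and secondary walls were lower in the same contrast (median -7.38, camera adjusted p = 8.66e-04, and adjusted p = 0.389 with an estimated correlation).

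Defence and phenylpropanoid genes moved in both directions with more members lower. Of 59 pathogenesis-related genes 15 were lower and 7 higher (20 and 10 adjusted over the list alone; median -0.40, adjusted p = 4.97e-04, and adjusted p = 0.389 with an estimated correlation). The callose-degrading beta-1,3-glucanase LOC_Os07g35560 averaged 0.25 ± 0.351 CPM in giant cells and 121 ± 69.3 in vascular cells (log2 -9.13, SE 1.5, adjusted p = 0.0226; SD, n = 4). The SCP-like copies LOC_Os07g03279, LOC_Os07g03368 and LOC_Os07g03458, counted among the lower ones, had near-equal values and may share reads, so their separate calls are uncertain. Of 19 phenylpropanoid and lignin genes 4 were lower and 2 higher (7 and 2 adjusted over the list alone; median -0.85, adjusted p = 0.00408, and adjusted p = 0.355 with an estimated correlation). Phenylalanine ammonia-lyase, the entry enzyme of the pathway, was lower at LOC_Os02g41650 (4.76 ± 5.85 against 229 ± 200 CPM, log2 -5.99, SE 1.04, adjusted p = 0.0264) and at the neighbouring LOC_Os02g41630 (7.87 ± 6.29 against 107 ± 54.4, log2 -4.21, SE 0.79, adjusted p = 0.0269). The 2 higher members were caffeoyl-CoA O-methyltransferases, LOC_Os08g05790 and LOC_Os08g38910, at 4.55 and 6.31 CPM in giant cells, chosen after their values were seen. Lower in the same contrast were the xylem and secondary wall markers (median -7.38, camera adjusted p = 8.66e-04, and adjusted p = 0.389 with an estimated correlation).

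Among regulators, WRKY72 (LOC_Os11g29870) averaged 0.396 ± 0.284 CPM in giant cells and 75.3 ± 135 in vascular cells (log2 -6.30, SE 1.42, adjusted p = 0.0269; SD, n = 4), and WRKY28 (LOC_Os06g44010) 0.375 ± 0.147 against 32.7 ± 35.9 (log2 -5.66, SE 1.46, adjusted p = 0.0271). Of 44 WRKY factors 3 were lower and 4 higher, the same adjusted over the list alone (median -0.89, adjusted p = 0.023, and adjusted p = 0.389 with an estimated correlation). Jasmonate genes had 1 member lower and 1 higher of 16, the same adjusted over the list alone (median -1.60, adjusted p = 0.00665, and adjusted p = 0.389 with an estimated correlation). Without vascular 14 dai replicate 4 the WRKY list had an adjusted p = 0.223, and without vascular 7 dai replicate 1 the jasmonate list had 0.0707.

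Trehalose-6-phosphate synthases split. LOC_Os05g44210 was higher (79.7 ± 12.7 against 1.27 ± 1.13 CPM, log2 6.03, SE 1.08; SD, n = 4), while LOC_Os09g20990 was lower (22.5 ± 8.03 against 212 ± 156, log2 -2.88, SE 0.62), both with adjusted p = 0.0269. Of 11 trehalose synthesis genes 3 were lower and 1 higher (4 and 1 adjusted over the list alone; median -0.81, adjusted p = 0.0321, and adjusted p = 0.389 with an estimated correlation). The list's adjusted p was 0.0607 without vascular 7 dai replicate 1, 0.223 without vascular 14 dai replicate 4, 0.0644 without giant 7 dai replicate 4, 0.0529 without giant 14 dai replicate 1 and 0.0701 without giant 14 dai replicate 4. Its median lay at percentile 27.2 of random lists matched on mean expression.

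Markers of xylem, which vascular captures could include, were lower in giant cells in 4 of 5 tested members, and in 4 adjusted over the list alone (median -7.38, adjusted p = 8.66e-04, and adjusted p = 0.389 with an estimated correlation). CESA9 (LOC_Os09g25490), a cellulose synthase of secondary walls, averaged 0.125 ± 0.174 CPM in giant cells and 56.9 ± 93.0 in vascular cells (log2 -8.48, SE 2.28, adjusted p = 0.0293; SD, n = 4). Of 7 phloem markers none passed the test (adjusted p = 0.431 for the list). Of 19 endodermis markers 3 were lower and 5 higher (3 and 6 adjusted over the list alone; adjusted p = 0.764), among them SCARECROW LOC_Os12g38490 at 2.4 ± 1.49 against 55.3 ± 37.6 CPM (log2 -4.44, SE 1.04, adjusted p = 0.0269).

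Of 25 DNA replication genes tested, 10 were higher and none lower (12 and 0 adjusted over the list alone). Their median log2 fold change was 3.53, or 2.63 with genes at 0 in either cell type at their bound (adjusted p = 0.0154, and adjusted p = 0.374 with an estimated correlation). The called members named here were weakly expressed, and weakly expressed models were often called higher. In 10000 random lists matched on mean expression, chosen after seeing the data, a list of this size had 6.1 members higher on average and a median of 2.28. The observed median lay at percentile 90.2 and the number of higher members at 95.3. The origin recognition subunit ORC4 (LOC_Os01g49010) averaged 4.63 ± 2.12 CPM in giant cells, the polymerase delta subunit POLD1 (LOC_Os11g08330) 2.58 ± 0.628 and MCM8 (LOC_Os05g38850) 2.57 ± 1.32 (SD, n = 4), all at 0 in every vascular library and chosen after their values were seen. The more abundant RFC1 (LOC_Os11g36390) averaged 27.2 ± 8.22 against 26.9 ± 42.8 CPM and did not pass (edgeR adjusted p = 0.285). The list's adjusted p was 0.062 without vascular 14 dai replicate 1.

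Of 61 gene models of the photosynthetic light reactions, 46 were copies of plastid genes that may share reads and 14 were nuclear genes. In all 14 were higher and 1 lower, and 18 and 1 adjusted over the list alone (median 1.68, adjusted p = 0.0011, and adjusted p = 0.441 with an estimated correlation). As a list chosen after seeing the data, the 14 nuclear genes had 6 higher and 1 lower (median 4.34). Their camera adjusted p was 0.0479 over 12 tests, and 0.189 with an estimated correlation. Except for ferredoxin--NADP reductase, each nuclear gene summed to at most 10.8 CPM in giant cells, and weakly expressed models were often called higher. The ycf3 copy LOC_Os01g57966 (chromosome 1, 33527626 to 33529604), described as a photosystem I assembly protein, averaged 1070 ± 568 CPM in giant cells and 138 ± 123 in vascular cells (log2 3.03, SE 0.51, adjusted p = 0.0245; SD, n = 4). The copy LOC_Os10g21254 averaged 1080 ± 571 against 141 ± 122; copies with near-equal values may share reads, so their separate values are uncertain. The lower member was the cytochrome b6-f iron-sulfur subunit LOC_Os07g37030, at 2.23 ± 1.00 against 45.1 ± 45.5 CPM, chosen after its values were seen.

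Transposon-derived models had 123 members higher and 46 lower of 1121 (0 and 7 adjusted over the list alone). Their median of 0.33 and mean of 0.70 lay above 0 but below the median of all tested models (0.98). Camera's list test, against other genes, was downward (adjusted p = 0.0315, and adjusted p = 0.389 with an estimated correlation). Fry, against no change, was upward (adjusted p = 0.0097). With the replicate number as a block camera's call was lost. The Ty3-gypsy model LOC_Os07g23640 averaged 6.8 ± 6.68 against 499 ± 362 CPM (log2 -6.34, SE 0.73, adjusted p = 0.00501; SD, n = 4). The list's adjusted p was 0.0607 without vascular 7 dai replicate 1, 0.106 without vascular 7 dai replicate 4 and 0.229 without vascular 14 dai replicate 1. Against the same kind of matched random lists, the medians of transposon models and of the lower lists other than trehalose synthesis lay at percentiles 0 to 0.4. Some lists that did not pass camera also lay low, with auxin at 0.9, ethylene at 1.2, terpenoid genes at 2.1, phloem at 3.2 and pectin at 4.1. Low percentiles were thus not particular to the lists that passed. The photosynthesis median lay at 100.

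**Figure D2:**
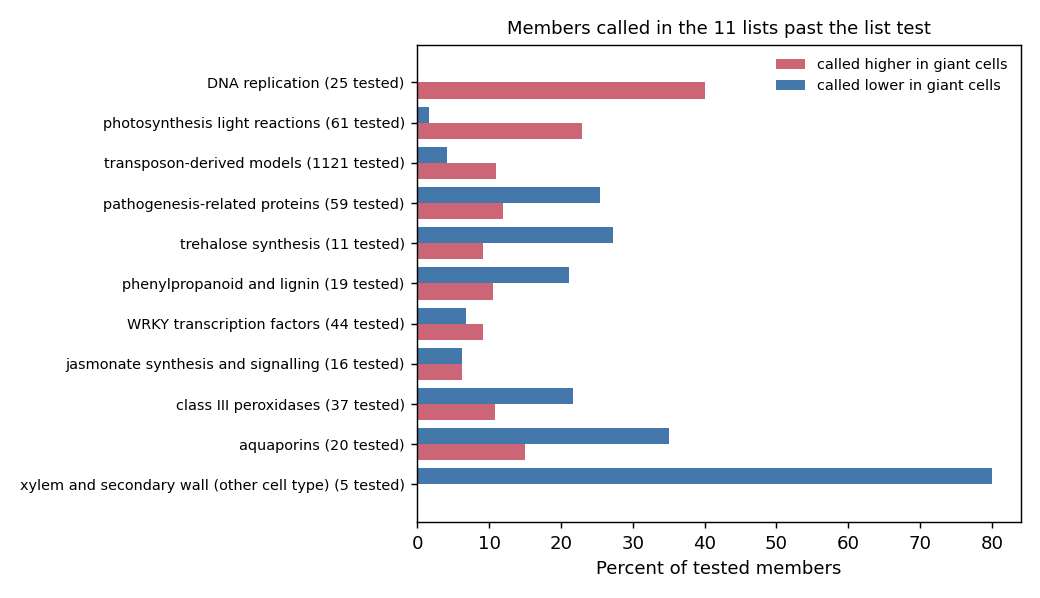
Percent of tested members of each gene list called higher (red) or lower (blue) in giant cells, mean of both days, for the 11 lists past camera's test with a preset correlation. DNA replication had 10 members higher and 0 lower of 25, and aquaporins 3 higher and 7 lower of 20.

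Sucrose synthase LOC_Os06g09450, which cleaves sucrose, was lower in giant cells at 68.7 ± 33.8 against 278 ± 62.5 CPM (log2 -2.10, SE 0.54, edgeR adjusted p = 0.027; SD, n = 4), though the sucrose cleavage list, with 4 higher and 2 lower of 17, did not pass (adjusted p = 0.605). Sugar transport had 1 higher and 1 lower of 13 (adjusted p = 0.297), and amino acid and peptide transport 15 higher and 4 lower of 72 (adjusted p = 0.754). In the auxin list (7 higher, 3 lower of 74, adjusted p = 0.177) the 5NG4-type LOC_Os01g36560 averaged 0.173 ± 0.162 against 88.3 ± 80.4 CPM (log2 -8.90, SE 1.14, adjusted p = 0.0073). In the gibberellin list (5 higher, 2 lower of 20, adjusted p = 0.615) the catabolic gibberellin 2-beta-dioxygenase LOC_Os01g55240 averaged 4.43 ± 4.57 against 284 ± 450 CPM (log2 -5.29, SE 1.42, adjusted p = 0.0294). In the ethylene list (9 higher, 2 lower of 42, adjusted p = 0.297) LOC_Os02g17680 averaged 70.0 ± 14.5 against 2.01 ± 1.1 CPM (log2 5.28, SE 0.90, adjusted p = 0.0245). The AINTEGUMENTA-like factor LOC_Os04g55970 of that list averaged 21.2 ± 16.0 CPM in giant cells, with at most 2 counts in a vascular library (adjusted p = 0.0269). Cytokinin genes had 4 higher and 0 lower of 19 (adjusted p = 0.868).

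Of the remaining lists, which did not pass camera's test, cellulose and callose synthesis had 5 members higher and 3 lower of 35 (adjusted p = 0.356) and pectin remodelling 7 and 8 of 37 (0.349). The 1,3-beta-glucan synthase LOC_Os06g51270, of the callose synthase family, averaged 34.6 ± 5.75 against 7.33 ± 13 CPM (log2 5.04, SE 1.34, edgeR adjusted p = 0.0288; SD, n = 4); its call was lost with the all-gene median set to 0. Core histones had 4 higher and 0 lower of 27 (0.615), cytosolic ribosomal proteins 11 and 2 of 125 (0.57), glutathione S-transferases 5 and 3 of 23 (0.943), and terpenoid phytoalexin genes 3 and 2 of 6 (0.594). Tetrapyrrole synthesis had 4 higher and 0 lower of 18 (0.158), the small RNA pathway 1 and 0 of 14 (0.707), and the Calvin cycle 0 and 0 of 9 (0.615). Adjusted over the list alone, the higher and lower members were 4 and 2 for sucrose cleavage, 0 and 1 for sugar transport, 20 and 11 for amino acid transport, 2 and 3 for auxin, 5 and 2 for gibberellin, 9 and 5 for ethylene and 4 and 0 for cytokinin. They were 5 and 3 for cellulose and callose, 13 and 8 for pectin, 0 and 0 for histones, cytosolic ribosomal proteins, the Calvin cycle and phloem, 7 and 4 for glutathione S-transferases, 3 and 3 for terpenoids, 4 and 0 for tetrapyrroles and 1 and 0 for small RNA.

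**Figure D3:**
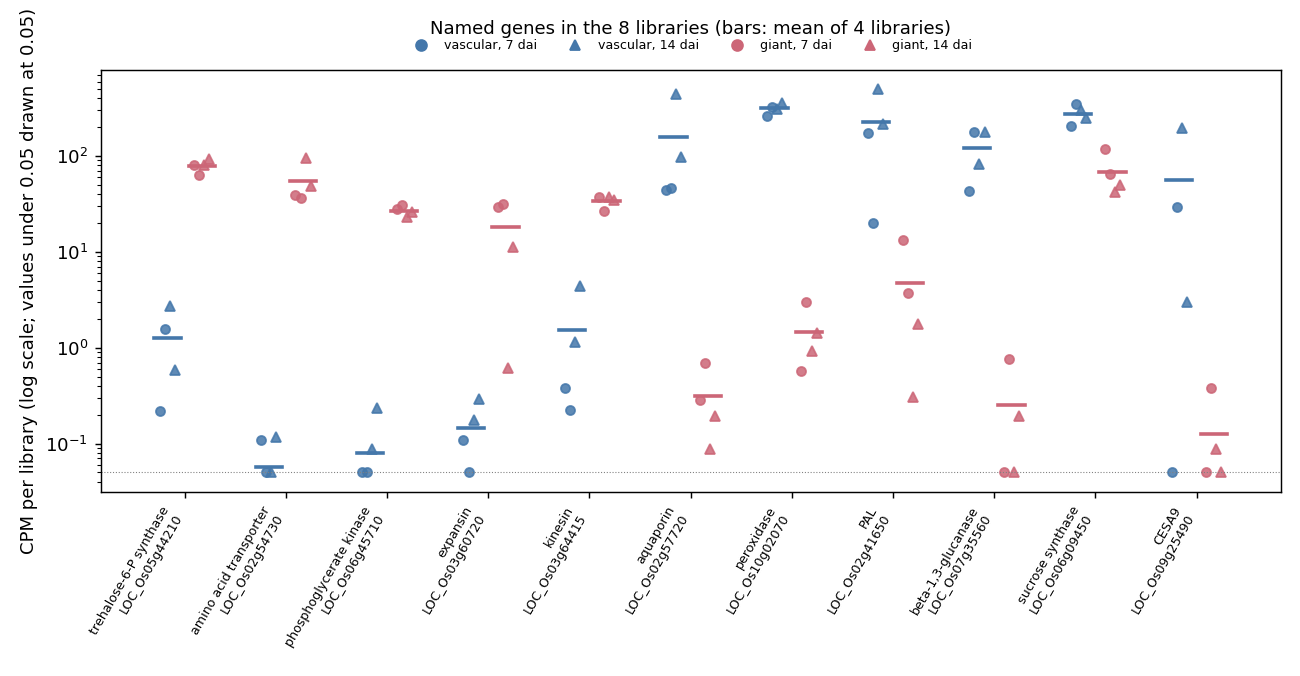
Normalised CPM of 11 genes in the 8 libraries on a log scale, with circles for 7 dai, triangles for 14 dai, blue for vascular cells, red for giant cells and a bar at the mean of 4 libraries; values under 0.05 are drawn at 0.05. The peroxidase LOC_Os10g02070 averaged 1.48 CPM in giant cells and 316 in vascular cells.

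**Figure D4:**
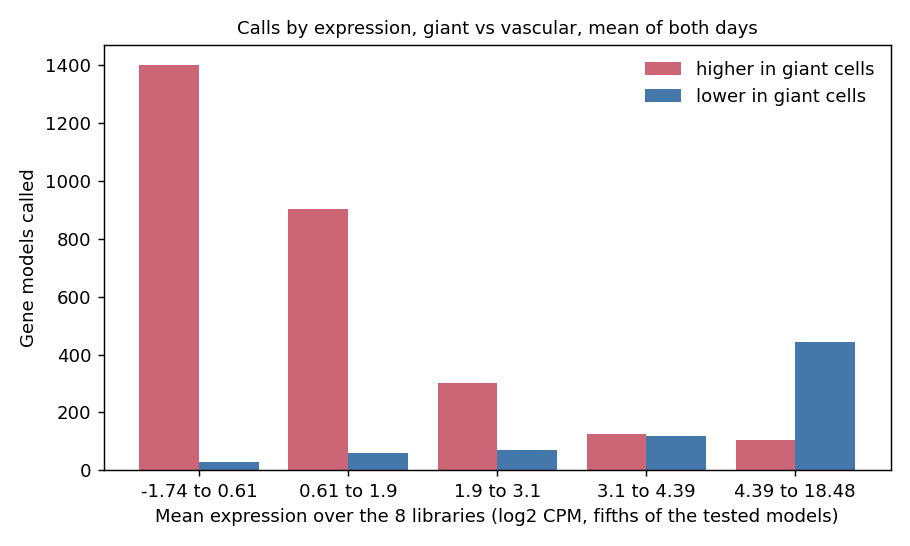
Gene models called higher (red) or lower (blue) in giant cells, mean of both days, in 5 equal bins of mean log2 CPM over the 8 libraries. The lowest bin held 1402 models called higher and 27 lower, and the top bin 106 higher and 442 lower.

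At 7 dai the giant to vascular contrast asks which genes differ early in feeding-site development. The peptidyl-prolyl isomerase LOC_Os02g02890, a protein-folding enzyme, averaged 11400 ± 913 CPM in giant cells and 277 ± 262 in vascular cells (SD, n = 2 each; log2 5.36, SE 0.89), but did not pass (edgeR adjusted p = 0.106). The translationally controlled tumour protein LOC_Os11g43900 averaged 4330 ± 2930 against 211 ± 119 CPM (log2 4.36, SE 0.73, adjusted p = 0.106). A kinase of the CAMK class, which includes calcium/calmodulin-dependent kinases, LOC_Os03g22050, averaged 12.8 ± 9.67 against 2150 ± 1020 CPM (log2 -7.39, SE 0.87, adjusted p = 0.0652), and a glycosyl hydrolase, LOC_Os05g15770, 4.27 ± 0.384 against 426 ± 179 (log2 -6.64, SE 0.95, adjusted p = 0.0896). edgeR called 0 genes, with 5018 at an unadjusted p under 0.05; DESeq2 called 3540 higher and 986 lower, and limma with a spread per cell type 2 higher and 239 lower. With the all-gene median set to 0 edgeR called 1 higher and 26 lower, LOC_Os03g22050 and LOC_Os05g15770 among them. With the replicate number as a block edgeR called 29 (6 higher, 23 lower). edgeR called 137 without the filter on low counts (40 higher, 97 lower), 4 without giant 7 dai replicate 1, 3 without giant 7 dai replicate 4 and 1 without giant 14 dai replicate 4.

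At the level of lists, 8 passed at 7 dai, each lost with an estimated correlation (adjusted p = 0.704 for photosynthesis and adjusted p = 0.431 with an estimated correlation for the other 7). Lower were peroxidases (median -3.0, or -3.41 with genes at 0 at their bound; adjusted p = 0.0014), pathogenesis-related genes (-1.50; 0.00584), aquaporins (-3.27, or -2.81; 0.00595), trehalose synthesis (-1.69; 0.0197), jasmonate (-2.15; 0.0276) and phenylpropanoid genes (-1.52; 0.0276). Higher were photosynthesis (1.91, or 1.83; 0.0197) and DNA replication (5.22, or 2.32; 0.0276). Adjusted over the list alone, 9 DNA replication genes were higher and 0 lower, and 10 pathogenesis-related genes were higher and 15 lower. The other counts adjusted over the list alone were 0 higher and 2 lower for aquaporins and for peroxidases, 6 and 0 for photosynthesis, 1 and 1 for trehalose synthesis, and 0 and 0 for jasmonate and phenylpropanoid genes. Without vascular 7 dai replicate 4, 0 lists passed, and 5 passed without vascular 7 dai replicate 1 or giant 7 dai replicate 4; without vascular 14 dai replicate 1 the phenylpropanoid list had an adjusted p = 0.0666.

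At 14 dai the same contrast asks which genes differ in older giant cells. The disease resistance protein RPM1 homologue LOC_Os11g11960 averaged 0.566 ± 0.0677 CPM in giant cells and 199 ± 2.55 in vascular cells (SD, n = 2 each; log2 -8.44, SE 1.20, edgeR adjusted p = 0.0863, not passed). The peroxidase LOC_Os10g02070 averaged 1.17 ± 0.357 against 335 ± 35.3 CPM (log2 -8.15, SE 1.17, adjusted p = 0.0863). In the other direction, the protein disulfide isomerase LOC_Os03g29240 averaged 60.9 ± 10.4 against 1.28 ± 1.07 CPM (log2 5.55, SE 1.14, adjusted p = 0.164), and the hemoglobin LOC_Os03g12510 averaged 118 ± 56.5 CPM in giant cells with at most 3 counts in a vascular library (adjusted p = 0.141). edgeR called 0 genes, with 4098 at an unadjusted p under 0.05; DESeq2 called 2694 higher and 866 lower, and limma with a spread per cell type 0 higher and 146 lower. With the all-gene median set to 0 edgeR called 1 higher and 24 lower, LOC_Os11g11960 and LOC_Os10g02070 among them. With the replicate number as a block edgeR called 24 (1 higher, 23 lower). edgeR called 149 without the filter on low counts (28 higher, 121 lower) and 16 without either giant 7 dai replicate 1 or giant 7 dai replicate 4 (1 higher and 15 lower each).

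At 14 dai 8 lists passed, each lost with an estimated correlation (adjusted p = 0.132 for aquaporins, adjusted p = 0.685 for photosynthesis and adjusted p = 0.466 with an estimated correlation for the other 6). Lower were aquaporins (median -3.44, or -3.25 with genes at 0 at their bound; adjusted p = 1.54e-06), xylem markers (-9.42, or -5.71; 6.81e-05), peroxidases (-3.03, or -2.02; 0.00214), pathogenesis-related genes (-1.16; 0.00225), phenylpropanoid genes (-0.92; 0.0244) and jasmonate genes (-2.02, or -2.64; 0.0425). Higher were photosynthesis (1.85, or 1.77; 0.00214) and DNA replication (3.42, or 2.34; 0.0425). Adjusted over the list alone, 5 xylem markers were lower and 0 higher, and 5 photosynthesis genes were higher and 0 lower. The other counts adjusted over the list alone were 0 higher and 1 lower for aquaporins and pathogenesis-related genes, 0 and 2 for peroxidases, 1 and 2 for phenylpropanoid genes, and 0 and 0 for jasmonate and DNA replication. Without vascular 7 dai replicate 4, 2 lists passed, without vascular 14 dai replicate 4, 3, and without vascular 14 dai replicate 1, 5. DNA replication also lost its call without vascular 7 dai replicate 1 (0.089), giant 7 dai replicate 1 (0.0581) or giant 14 dai replicate 4 (0.13), jasmonate without the same 3 libraries (0.0604, 0.0581 and 0.0556), and phenylpropanoid genes without giant 14 dai replicate 1 (0.0671), while aquaporins kept theirs with each library left out. Xylem markers kept theirs in the 6 fits that tested them. Without vascular 7 dai replicate 4 or vascular 14 dai replicate 1 fewer than 5 members were tested. With the replicate number as a block 5 lists passed, and DNA replication, jasmonate and phenylpropanoid genes lost their call.

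Whether the giant to vascular contrast differed between 14 and 7 dai was tested as a difference of both contrasts. The 3 genes with the smallest p in each direction, chosen without the separation rule used elsewhere, were led by vascular values that differed between days. The uricase LOC_Os01g64520, a purine-degrading enzyme, averaged 203.8 ± 70.3 CPM in vascular cells at 7 dai and 5.33 ± 0.0356 at 14 dai, against 18.8 ± 5.39 and 28.7 ± 7.24 in giant cells (SD, n = 2; log2 difference 5.86, SE 1.38). The SNARE protein LOC_Os02g02720 averaged 0.037 ± 0.0523 CPM in vascular cells at 7 dai and 119.9 ± 84.1 at 14 dai, against 14.2 ± 5.37 and 18.3 ± 3.43 in giant cells. Neither passed (edgeR adjusted p = 0.469 each). edgeR called 0 genes, with 1826 at an unadjusted p under 0.05; limma called 0 as well, DESeq2 called 965, and edgeR without the filter on low counts 27. None of 33 lists passed; without vascular 14 dai replicate 1, 2 did, and without vascular 7 dai replicate 4, 1 did. Across genes the log2 fold changes at 7 and 14 dai, which share no library, correlated with Pearson r = 0.473 and Spearman rho = 0.441, and 65.27% had the same sign. Both contrasts had an all-gene median above 0 (0.85 at 7 dai and 0.57 at 14 dai) and used the same filter on low counts. Genes with few counts in vascular libraries of both days can also raise these values, so they are not evidence for single genes.

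Within giant cells, 14 dai was compared with 7 dai to follow their development. The heat shock protein LOC_Os09g30412 averaged 75.7 ± 21.3 CPM at 14 dai and 1250 ± 135 at 7 dai (SD, n = 2 each; log2 -4.04, SE 0.77), and its neighbour LOC_Os09g30418 averaged 69.5 ± 19.7 against 993 ± 202, though these neighbouring copies have near-equal values and may share reads. The hemoglobin LOC_Os03g13140 averaged 469 ± 456 against 2.79 ± 2.24 CPM (log2 7.39, SE 1.70). None of these passed (edgeR adjusted p = 1). edgeR called 0 genes with 177 at an unadjusted p under 0.05; DESeq2 called 25, limma with a spread per cell type 141 and edgeR without the filter on low counts 3. A fit to the 4 giant cell libraries alone, chosen after seeing the data, called 10 genes higher and 14 lower at 14 dai, among them LOC_Os09g30412 (adjusted p = 0.0258) and LOC_Os03g13140 (adjusted p = 0.0339).

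Among lists in that comparison, photosynthesis was higher at 14 dai (median 1.05, adjusted p = 1.94e-19), while cytosolic ribosomal proteins (-0.62, 1.46e-04), expansins (-0.21, 0.00492), xylem markers (-3.12, or -2.14 with genes at their bound, 0.0106) and plastid ribosome genes (-0.39, 0.0364) were lower. In lists chosen after seeing the data, all 98 copies of plastid genes, which may share reads and make up 46 of the 61 photosynthesis members, had a median of 1.09, while 14 nuclear photosynthesis genes had 0.36 (camera adjusted p = 0.953 over 12 tests). In vascular cells the photosynthesis list had a median of 1.25 over the same days without passing (adjusted p = 0.173), and its day difference was -0.29 (adjusted p = 0.993). Each of the 5 fixed lists was lost at adjusted p = 0.567 with an estimated correlation, and no member passed alone or adjusted over the list alone (0 higher, 0 lower in each). The 60S ribosomal protein L27a-3, LOC_Os02g07890, averaged 0.207 ± 0.0176 against 4.44 ± 2.16 CPM, and the expansin LOC_Os03g44290 0.0648 ± 0.0916 against 4.19 ± 0.945 (SD, n = 2), both chosen after their values were seen. Without giant 7 dai replicate 1 the expansin list had an adjusted p = 0.787, the plastid ribosome list 0.0852 and the xylem list 0.0646. Without giant 14 dai replicate 1 the plastid ribosome list had 0.729, and without giant 14 dai replicate 4 the cytosolic ribosomal list had 0.0642. Leaving out vascular libraries, which changes the shared spread, gave the expansin list 0.118, 0.0625 and 0.0519 without vascular 7 dai replicate 1, vascular 7 dai replicate 4 and vascular 14 dai replicate 1. It gave the plastid ribosome list 0.102 and 0.0718 without vascular 7 dai replicate 1 and vascular 7 dai replicate 4, and the xylem list 0.0742 without vascular 14 dai replicate 4.

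Within vascular cells of mock-inoculated roots, 14 dai against 7 dai gives the change of the control with age. The translation factor SUI1 LOC_Os01g09890 averaged 63.8 ± 35 CPM at 14 dai and 0.0548 ± 0.0776 at 7 dai (SD, n = 2 each), and the pentatricopeptide repeat protein LOC_Os10g02650 averaged 75.9 ± 45.6 against 0, at least 393-fold higher against the floor of 3 counts per library. The protein disulfide isomerase LOC_Os03g29240 averaged 1.28 ± 1.07 against 85.1 ± 20.7 CPM (log2 -6.03, SE 1.16). None passed (edgeR adjusted p = 0.261). edgeR called 0 genes with 3049 at an unadjusted p under 0.05; limma called 0, DESeq2 3005 and edgeR without the filter on low counts 110. A fit to the 4 vascular libraries alone, chosen after seeing the data, called 0 with 422 at an unadjusted p under 0.05. None of 33 lists passed; without vascular 14 dai replicate 1, 1 did.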

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

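The tests in this part were chosen after the result was seen. Unannotated regions, which were not among the features tested above although most overlap a gene model, carried a signal. In a fit that included them, 2211 of 7239 tested regions were higher in giant cells and 189 lower (edgeR, mean of both days, adjusted p under 0.05). How the regions were defined is not given. Giant cell libraries detected 13590 ± 1160 regions and vascular libraries 4989 ± 1100 (SD, n = 4). If regions were found in these same libraries, part of the excess may come from that choice, which was not tested. The region LCM_1.33916 (chromosome 9, 13765181 to 13765967), which overlaps no gene model, averaged 20.5 ± 9.01 CPM in giant cells and 0.165 ± 0.154 in vascular cells (SD, n = 4; log2 7.55, SE 1.62, edgeR adjusted p = 0.0287). LCM_1.656 (chromosome 1, 4883464 to 4883734), which overlaps a gene model, averaged 19.8 ± 11 CPM and was at 0 in vascular libraries. Of the regions called higher 1412 (63.9%) overlap a gene model, against 59.5% of those tested.

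Genomic DNA in giant cell libraries would give regions a larger share of their counts; the share of all counts was 5.29% ± 1.23 in giant cells and 6.03% ± 0.692 in vascular cells (SD, n = 4, two-sided exact permutation p = 0.286), and outside the 2 highest models it was 10.36% ± 1.29 and 14.55% ± 1.55 (p = 0.0286, adjusted p = 0.05 over 7 measures). Neither share was higher in giant cells, but each sums over all regions and the first did not separate the cell types, so DNA behind weakly expressed regions cannot be told apart from transcription. Whether the regions share the imbalance of weakly expressed gene models also stays open: of 5 expression bins the widest gap in the percent of tested features called higher was 6.1 points, in the lowest bin (50.7% of regions, 44.6% of gene models). Among calls the percent higher was near its limit in the lowest bin (99.1% for regions, 98.5% for gene models) and differed in the 2 top bins (41.7% against 58.4%, and 2.6% against 19.2%). Whether giant cells transcribe these regions, and so a biological difference between the cell types or between inoculated and mock-inoculated roots, was not tested.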

How the results depend on the processing

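No named gene reversed direction under the alternatives run, and no list that passed did so where lists were rerun. Lists were rerun only with the replicate block, DESeq2 size factors, upper-quartile factors and each library left out, so not with limma. The balance of gene calls in the mean of both days did reverse. It went from 2839 higher and 716 lower to mostly lower without either of the 7 dai giant cell libraries, and to 25 and 344 with limma. The calls of the mean of both days moved from 3555 to 1538 at 5 CPM, where fewer genes are tested, to 6184 with DESeq2 and, chosen after seeing the data, to 369 with limma with a spread per cell type; leaving out each library gave 37 to 4754. A fit with regions included made 6016 calls, of which 3616 were gene models. At 7 dai the 0 calls became 29 with the replicate block, 137 without a filter, 4526 with DESeq2 and 241 with limma, and 27 with the all-gene median set to 0 (0 to 4 leaving out each library). At 14 dai they became 24, 149, 3560, 146 and 25 (0 to 16). The day difference gave 27 without a filter and 965 with DESeq2. In giant cells 14 against 7 dai gave 3 without a filter, 25 with DESeq2, 141 with limma and 24 in a fit to giant cells alone, and in vascular cells 110 without a filter and 3005 with DESeq2; leaving out each library gave 0 in all 3. Lists passed in 8 of 33 tests at 14 dai, and in 5 with the replicate block; leaving out each library gave 0 to 11 at 7 dai, 2 to 9 at 14 dai, 8 to 11 for the mean, 0 to 2 for the day difference, 2 to 7 in giant cells and 0 to 1 in vascular cells. With the block, DNA replication (0.0686), jasmonate (0.0595) and phenylpropanoid genes (0.0504) lost their call at 14 dai, transposon models (0.0577) in the mean and plastid ribosome genes (0.0763) in 14 against 7 dai in giant cells. The replicate numbers gave no sign of pairing (correlations -0.038 to 0.056), though noise between vascular libraries could hide it. Otherwise the cause was not tested. Over 32 list results, 91 of 96 planned values kept their call and 191 of 250 did so with a library left out; for the 63 called of 97 gene results, 367 of 377 and 310 of 498 did, and 216 of 252 under the alternatives added later. The gene results not called became calls in 69 of 220 planned values, 14 of 270 with a library left out and 29 of 148 of those added later. Fold sizes moved too: of 63 called genes of the mean of both days, 58 moved by over 1.5 times with the all-gene median set to 0 and 32 with limma. Where a library was left out of a group, the lone other is assumed to vary like the other groups. With 3 or fewer counts in vascular libraries, 1 to 3 reads decide a value, so folds of weakly expressed genes are not measured at this depth.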

Other observations

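All tests of explanations in this part, and the gene lists of organelle copies, were chosen after the result was seen; the lists of nuclear gene groups were fixed beforehand. The list of cyclins and cell division genes had 16 members higher and 1 lower of 73 (17 and 1 adjusted over the list alone) without passing camera's test (adjusted p = 0.118). Among the higher members was the kinesin LOC_Os03g64415, a microtubule motor, which averaged 33.9 ± 4.81 CPM in giant cells and 1.53 ± 1.93 in vascular cells (SD, n = 4; log2 5.19, SE 1.17, edgeR adjusted p = 0.0269). The lower member was the cyclin-dependent kinase G-1 LOC_Os02g39010, at 85.7 ± 28.1 against 400 ± 59.4 CPM (log2 -2.23, SE 0.49, adjusted p = 0.0269). It entered because the words that define the list take in any gene described as cyclin-dependent, so the list is broader than its name. Expansins and xyloglucan genes, which loosen walls, had 8 higher and 1 lower of 20 (10 and 1 adjusted over the list alone; adjusted p = 0.349), with LOC_Os03g60720 at 18.2 ± 14.9 against 0.144 ± 0.122 CPM (log2 6.75, SE 1.69, adjusted p = 0.027). Chaperones had 21 higher and 3 lower of 131 (19 and 2 adjusted over the list alone; adjusted p = 0.458), with the DnaK protein LOC_Os03g02260 at 28.8 ± 8.87 against 0.71 ± 1.31 CPM (log2 6.93, SE 1.61, adjusted p = 0.0269). In 10000 random lists matched on mean expression the chaperone median lay at percentile 99.9 and that of cyclins and cell division at 98.9. Their numbers of higher members lay at 78.4 and 96.3. The expansin median lay at 74.5 and that of plastid ribosome and division genes at 78.6, with higher members at 86.9 and 95.7. Cytosolic ribosomal proteins also had a median at 98.9, with higher members at 13.8. These percentiles were chosen after the result was seen and not adjusted over 33 lists, and they take no account of correlation between members. Plastid ribosome and division genes had 8 higher and 0 lower of 24, the same adjusted over the list alone (adjusted p = 0.297). Fry, against no change, passed cyclins and cell division (adjusted p = 3.94e-04), expansins (2.17e-04), chaperones (6.54e-04) and plastid ribosome genes (0.00829) upward. The median of all tested models also lay above 0 (0.98). The calls of the 4 genes named in this paragraph were lost without giant 7 dai replicate 1 and without giant 7 dai replicate 4.

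The mitochondrial ATP synthase alpha copy LOC_Os01g08350 averaged 2264 ± 154 CPM in giant cells and 5479 ± 1400 in vascular cells (SD, n = 4; log2 -1.25, SE 0.29, edgeR adjusted p = 0.0269). Of 12 tested copies of mitochondrial genes 2 were lower and none higher, with a median of -0.96 (camera adjusted p = 2.67e-08 over 12 tests of organelle lists). The list's call was lost with an estimated correlation (adjusted p = 0.141), and with copies summed per gene none of 9 mitochondrial genes passed (lowest adjusted p = 0.0858, exact permutation test). Within giant cells copies of plastid genes were higher at 14 than at 7 dai as a list (median 1.09, camera adjusted p = 3.42e-42), a call lost with an estimated correlation (adjusted p = 0.141), with 0 of 98 copies passing alone; these are copies of 26 genes and not separate measurements. Copies of mitochondrial genes had a median of 0.44 in the same comparison (camera adjusted p = 2.42e-07, also lost at adjusted p = 0.141 with an estimated correlation), with 0 of 12 passing alone, and 14 nuclear photosynthesis genes a median of 0.36 (adjusted p = 0.953).

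Calls in the mean of both days were mostly higher at low expression (98.1% of calls in the lowest of 5 equal bins) and mostly lower at high expression (19.3% higher in the top bin). At equal reads outside the 2 highest models 98.8% of the lowest bin's calls and 24.7% of the top bin's were higher, so unequal depth does not account for the trend. With the all-gene median set to 0 the share was 97.9% in the lowest bin, 55.2% in bin 3, 15.3% in bin 4 and 3.1% in the top bin (1971 higher and 1303 lower in all). Rescaling moves all bins alike, so the share in the lowest bin, whose median was 4.55, could hardly fall. Bin medians still ran from 4.48 to -2, but the balance in the other bins depends on scaling. Models can pass the filter on low counts through giant cell libraries alone, and the effect of this on the lowest bin was not tested. Vascular libraries drawn at random from the giant cell profile gave 0 calls, but the profile and the loss are assumed, so uneven loss of molecules in capture or amplification of vascular RNA cannot be told apart from a broader transcriptome of giant cells; of the 2839 genes called higher, 2740 had 3 or fewer counts in at least 1 vascular library. A biological difference between the cell types, or between inoculated and mock-inoculated roots, stays open and was not tested separately. Of the 35 splits into 4 and 4 only 1, the real one, gave as many calls (3335 with a single term for the groups, against 0 in the highest other). Every other split mixes the cell types, so any difference between them adds to the spread and few calls could arise there. The splits therefore do not exclude chance, and some captures may share a plant.

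Copies of plastid genes annotated in the nuclear genome were higher in giant cells in 18 of 98 cases, from 7 of 26 plastid genes; the 5 copies of ycf3 summed to 5200 ± 2740 CPM against 675 ± 599 (SD, n = 4, two-sided exact permutation p = 0.0286, the smallest possible, and adjusted p = 0.0744 over 26 plastid genes). Copies of the same gene correlated over the 8 libraries at a median r of 0.996, against 0.645 between different plastid genes, which is consistent with reads of a plastid transcript being counted at several copies. A higher yield of all plastid transcripts by the same factor would leave the ratio of photosystem to RNA polymerase subunits alike, but its log2 value was 2.03 ± 0.21 in giant cells and 0.71 ± 0.66 in vascular cells, a difference of 1.32 (exact permutation p = 0.0286). The photosystem subunit psbB differed by -0.04 and polymerase subunits alpha and beta by 0.48 and 0.12, and over all 26 genes the log2 differences had an SD of 1.18, against 0.998 in the highest other of 35 splits. Plastid DNA and a different plastid type or state in giant cells stay open and were not tested separately.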
